A study of Homo sapiens with 6 samples.

How the data were processed

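Total RNA of Y79 retinoblastoma cells was labelled with biotin and hybridised to Illumina HT-12 v4 arrays, per the labels' protocols. The 6 arrays fall by their labels into 3 untreated and 3 treated with Tiam1 siRNA for 48 hours, at passages 25, 27 and 29 in each group. The deposited probe profile gives per array the mean bead intensity of 47322 probes, with no background subtraction or normalization seen in the values, and a detection p-value per probe, per the file headers. The software behind it is not given in the sources used here. The deposited value table is on the log2 scale. Each probe's median over the untreated arrays is 0 within 0.0051 in 100% of its rows, and its values correlate with scanner signals centred likewise at 0.885 to 0.972 across probes, with slopes of 0.91 to 0.961. This gives its scale, centring and direction, and its normalization between arrays stays unknown. The column medians were 0, 0 and 0.03 for the untreated arrays of passages 25, 27 and 29, and 0.01, -0.06 and 0 for the arrays labelled Tiam1 siRNA. A further 12 per-sample columns, holding array numbers and spreads, were not used.

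Scanner intensities were background corrected by normexp with the background inferred from the detection p, offset by 16, quantile normalized and put on the log2 scale with limma 3.58.1 in R 4.3.3. An offset compresses the changes of dim probes. Probes with a detection p under 0.01 on at least 3 of the 6 arrays were kept, which left 16858. Names came from the file, updated through RefSeq genes of assembly GRCh38.p14, used here for names and for gene spans without coordinates. By accession 27606 probes matched, by symbol 3387 and by synonym 1387. The file's own symbol was kept for 11580, 3270 had no name and 92 were spike-in controls. Of the kept probes 480 had no symbol. The brightest probe stood for each gene, which gave 12866 genes. Chromosomes are those in the probe profile.

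Groups were compared with lmFit and eBayes in limma, Benjamini-Hochberg adjustment and a threshold of 0.05, without a block. Fold changes are arrays labelled Tiam1 siRNA minus untreated on this log2 scale. The 33 gene lists were written before the data were examined, as were the designs and most alternatives. Of these, 32 had at least 5 tested genes, and the red cell list had 2 and was not tested. Lists were tested with camera at a preset correlation of 0.01, with camera at an estimated correlation and with fry. No list passed with an estimated correlation or in fry's directional test. Counts per array were compared by an exact permutation test.

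Named genes were chosen by a rule fixed before the data were examined. TIAM1 came first. Genes past the threshold with the same sign at all 3 passages came next, and where fewer than 5 passed in a direction, the 8 with the smallest p and the same sign were given as values. Up to 4 members with the smallest p were named from each list that passed and from the lists on Rac1, actin, adhesion, apoptosis, cell cycle, interferon and photoreceptors. Unnamed loci were passed over, as were XIST and Y-linked genes. The result of 1 further list with its members and of 1 gene is not reported here. A gene not detected on any array of a group has only a bound there.

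No arrays were duplicates, as at most 0.00211% of values were identical between any 2 arrays.

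Alternatives covered background correction, normalization, the detection filter, the rule for probes, the variance model, array weights, passage as a block, the authors' value table and leaving out each array and each passage. The fit was tested on simulated data for the 12866 genes, with 200 changed genes in each of 5 draws. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.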

Results

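Gene expression was measured in Y79 cells, a line established from human retinoblastoma that grows in suspension, on Illumina HT-12 v4 bead arrays. Tiam1 is a guanine nucleotide exchange factor that activates the small GTPase Rac1. The series asked which genes Tiam1 silencing regulates, by comparing cells treated with Tiam1 siRNA for 48 hours with untreated cells. Each group held 3 arrays, 1 each at passages 25, 27 and 29. Of the 47322 probes on each array, between 16410 and 17382 were detected above background, and the median signal lay between 66.7 and 71.7 intensity units. The number of detected probes was 16873 ± 453 on untreated arrays and 16630 ± 251 on arrays labelled Tiam1 siRNA (mean ± SD, n = 3), a difference of -243 (exact two-sided permutation test, p = 0.6; 3 against 3 arrays cannot go below 0.1). The number of arrays limits the precision of every comparison. Nothing beyond the passage says that the arrays came from separate cultures, so p-values measure the spread between these samples, which may be technical.

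The targeted transcript was examined first. TIAM1 on chromosome 21 was read by 1 probe (ILMN_1655577), which was detected on all 6 arrays. Its normalized log2 signal was 7.20 ± 0.26 on untreated arrays and 7.08 ± 0.03 on arrays labelled Tiam1 siRNA (mean ± SD, n = 3). The log2 change was -0.11 (SE 0.13), with a 95% interval from -0.40 to 0.17, and it did not pass the limma test (adjusted p = 0.943). The TIAM1 signal was lower by label at passages 25 and 27, with differences of -0.32 and -0.23, and higher at passage 29, with a difference of 0.21. Because passage 29 went against its label, samples are called arrays labelled Tiam1 siRNA throughout, and every direction given here is by label. Without the untreated array of passage 29 the log2 change of TIAM1 was -0.26, and without both arrays of passage 29 it was -0.27, and neither passed over all genes. The comparison was with untreated cells, so an effect of transfection or of siRNA in general cannot be separated from an effect of Tiam1 silencing.

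**Figure D1:**
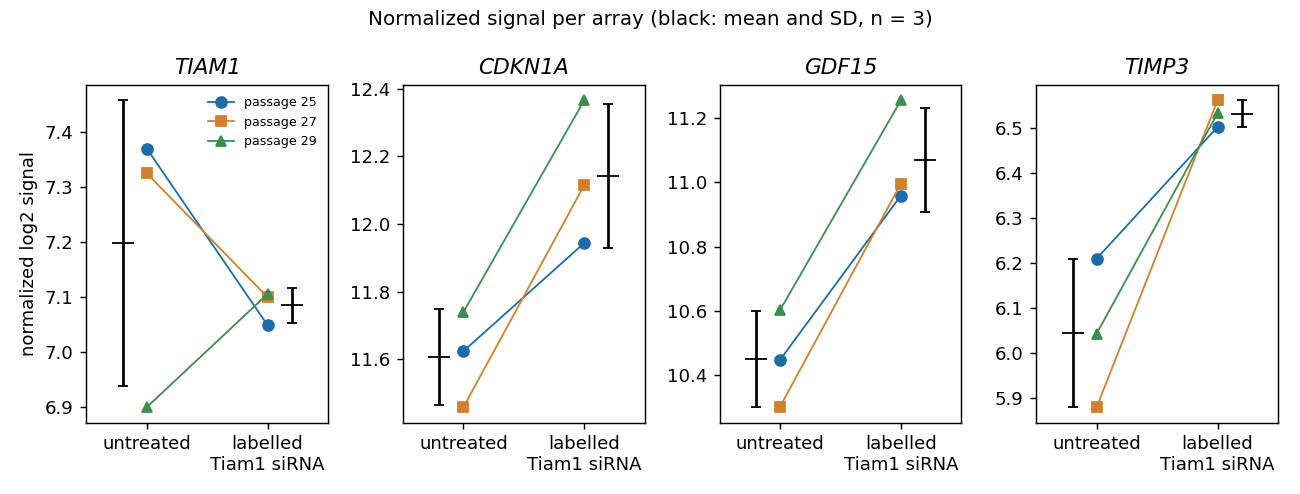
Normalized log2 signal (y axis) of TIAM1, CDKN1A, GDF15 and TIMP3 on each untreated array and each array labelled Tiam1 siRNA (x axis), with lines joining the arrays of one passage and black bars giving the mean and SD of 3 arrays. TIAM1 differs by -0.32, -0.23 and 0.21 at passages 25, 27 and 29, whereas the other genes shown are higher by label at every passage.

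No single gene passed the test between arrays labelled Tiam1 siRNA and untreated arrays. Of 12866 genes tested with limma, 0 had an adjusted p under 0.05, and the smallest adjusted p was 0.740. At an unadjusted p under 0.05 there were 748 genes, 449 higher and 299 lower by label, where 643 would be expected with no difference. The higher share was 60.0%, and it was 54.0% under median scaling, 53.7% on the authors' value table, 50.1% without the array labelled Tiam1 siRNA of passage 27 and 47.5% without both arrays of that passage. A change of at least 1.5-fold was measured for 12 genes, 7 higher and 5 lower, and the largest was 1.75-fold. In 1432 genes (11.1%) the values of the groups did not overlap, where chance gives 10% for 3 against 3. The difference had the same sign at all 3 passages in 27.3% of genes, where chance gives 25%. In simulated arrays with means taken from the data, 200 changed genes were planted in each of 5 draws. Noise was normal and independent between genes, with SDs that limma had drawn toward a common value. The simulated arrays held no passage effect and no array that stands apart. The same limma fit called 86.3% of genes changed by 1.5-fold, 100% of those changed by 2-fold and 4.18% of those changed by 1.2-fold. False calls numbered 50 over all draws. These shares depend on the number of changed genes planted. They are not the power of the real comparison, where 0 of the 12 genes measured at 1.5-fold or more passed.

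The genes with the smallest p are given as values, not as calls. Those measured higher by label at every passage included TNNC2, a fast skeletal muscle troponin C, with a log2 change of 0.59 (SE 0.10), and MT1F, a metal-binding metallothionein, with 0.70 (SE 0.12). GDF15, a secreted stress-responsive member of the TGF-beta family, had a log2 change of 0.62 (SE 0.12). The neuronal RNA-binding protein gene ELAVL3 had 0.50, ANKRD52 had 0.55 and GAL3ST4 had 0.49. PHLDB3 (0.66) and CRISPLD2 (0.53) were each detected on 2 of 3 untreated arrays. Without background correction the values were 0.35 for TNNC2, 0.38 for PHLDB3, 0.35 for ANKRD52 and 0.30 for CRISPLD2. MT1F belongs to a family of near-identical copies, so its probe may also read related transcripts.

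Those measured lower by label at every passage included DCUN1D1, which promotes cullin neddylation, with a log2 change of -0.46 (SE 0.10), and HOOK3, a microtubule-linked adaptor, with -0.47 (SE 0.10), or -0.28 without background correction. The transcriptional corepressor gene CTBP2 had -0.47 (-0.28 with the mean of a gene's probes), IMPA1 had -0.41 and the mitochondrial carrier gene SLC25A46 had -0.39. WASHC2A, a subunit of the actin-nucleating WASH complex with close paralogs, had -0.73 (SE 0.17), and EXOSC8, a subunit of the RNA exosome, had -0.62 (SE 0.15). GET3 was detected on 3 of 3 untreated arrays and on 0 of 3 arrays labelled Tiam1 siRNA, and was at least 1.21-fold lower by label, taking the lowest detected signal of an array as the bound. The adjusted p in limma was 0.740 for each of the genes with the smallest p in either direction.

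Among 32 gene lists fixed before the data were examined, 4 passed camera with a preset correlation of 0.01. The p53 target list shifted upward in arrays labelled Tiam1 siRNA (camera adjusted p = 0.000229), with 18 of 21 measured members higher and 3 lower and a mean log2 change of 0.17. With an estimated correlation the list did not pass (adjusted p = 0.609), nor did it in fry (adjusted p = 0.243). CDKN1A, the cyclin-dependent kinase inhibitor p21, had a log2 change of 0.53 (SE 0.12). The death receptor gene TNFRSF10B had 0.27, the pro-apoptotic gene BAX 0.23 and ZMAT3 0.26. With the mean of a gene's probes TNFRSF10B had 0.11. Adjusted over the list alone, 1 member passed (CDKN1A, adjusted p = 0.0359), and 0 passed over all genes tested. The list's median difference was 0.12, 0.14 and 0.23 at passages 25, 27 and 29.

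The adhesion and invasion list also shifted upward by label (camera adjusted p = 0.0250; adjusted p = 0.609 with an estimated correlation), with 19 of 28 members higher and 9 lower. TIMP3, an inhibitor of matrix metalloproteinases, had a log2 change of 0.49 (SE 0.10), the laminin chain gene LAMC1 had 0.33, the neural adhesion molecule gene L1CAM 0.25 and TIMP2 0.24, which was 0.11 with the mean of a gene's probes. TIMP3 and TIMP2 restrain matrix breakdown, and LAMC1 encodes a basement membrane component. TIMP3 had 0.31 without background correction. Adjusted over the list alone, 1 member passed (TIMP3, adjusted p = 0.0231), and 0 passed over all genes. Without both arrays of passage 29 the list's adjusted p was 0.434, and it was 0.264 without the untreated array of that passage and 0.158 without its array labelled Tiam1 siRNA. It was 0.0956 without the untreated array of passage 27 and 0.0525 without that passage's array labelled Tiam1 siRNA, 0.114 without both, and 0.0541 with array weights. The list's mean log2 change was 0.079, 0.085, 0.079 and 0.088 in these fits, against 0.090 with all arrays unweighted. It was 0.053 without both arrays of passage 29.

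The MYC target list (camera adjusted p = 0.0154) and the proteasome list (camera adjusted p = 0.0199) shifted downward by label. Both had an adjusted p of 0.609 with an estimated correlation. In the MYC list 26 of 32 members were lower and 6 higher, with log2 changes of -0.24 for the translation factor gene EIF5A, -0.22 for PPAN, -0.16 for the polyamine enzyme gene ODC1 and -0.15 for NOP56. In the proteasome list 28 of 31 members were lower and 3 higher, with -0.38 for PSMD11, -0.33 for PSMD3, -0.35 for PSMD8 and -0.17 for PSMC1. Without both arrays of passage 29 the values were -0.11 for EIF5A, -0.06 for PPAN, -0.08 for NOP56, -0.19 for PSMD11, -0.13 for PSMD3 and -0.12 for PSMD8. Without the untreated array of that passage alone they were -0.14 for EIF5A and for PPAN, -0.19 for PSMD3 and -0.20 for PSMD8, and PPAN had -0.14 without its array labelled Tiam1 siRNA. At passage 25 the difference was 0.04 for PSMD8 and 0.09 for EIF5A. In both lists 0 members passed, adjusted over the list alone or over all genes. At passage 25 the median differences were 0.01 for the MYC list and -0.0046 for the proteasome list, against -0.12 for both at passage 29. Without both arrays of passage 29 the adjusted p was 0.512 for the MYC list and 0.223 for the proteasome list. The MYC list did not pass without the array labelled Tiam1 siRNA of passage 27 (adjusted p = 0.0525) or of passage 29 (0.176), or without the untreated array of passage 29 (0.120), and the proteasome list did not pass without the untreated array of passage 27 (0.0956) or the array labelled Tiam1 siRNA of passage 29 (0.184). Without both arrays of passage 27 the adjusted p was 0.0829 for the MYC list and 0.114 for the proteasome list, and with array weights it was 0.0541 for the MYC list. The mean log2 changes without passage 27 were -0.084 (MYC) and -0.079 (proteasome), against -0.075 and -0.076 with all arrays. Without both arrays of passage 29 they were -0.017 and -0.039.

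**Figure D2:**
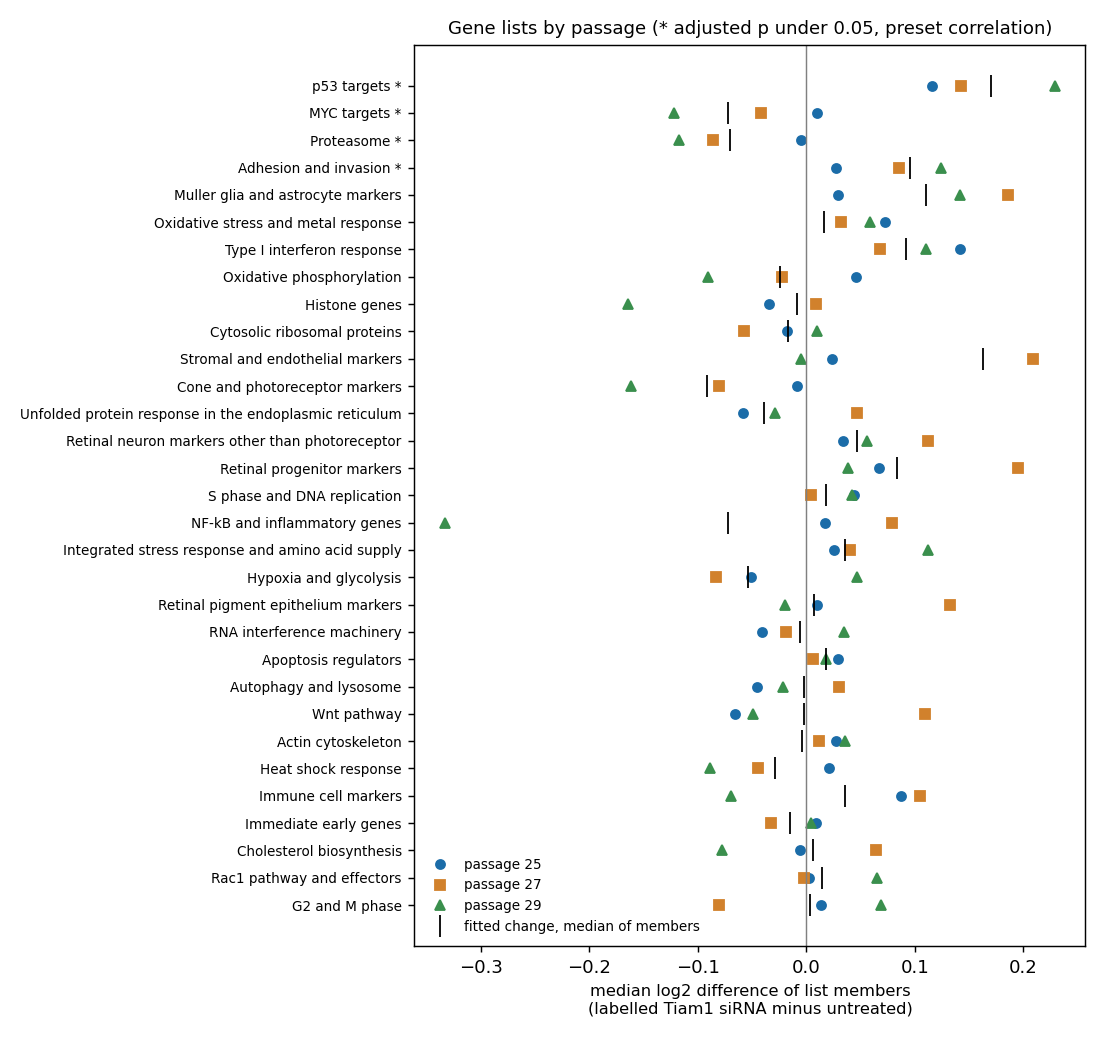
Median log2 difference of list members (x axis, labelled Tiam1 siRNA minus untreated) for the gene lists reported here (y axis, ordered by p), with coloured points for passages 25, 27 and 29 and a black bar for the median fitted change. The p53 target list has medians of 0.12, 0.14 and 0.23, all above 0, and an asterisk marks the 4 lists with an adjusted p under 0.05 at the preset correlation.

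Lists on the pathway in which Tiam1 acts did not pass. In the Rac1 list (adjusted p = 0.934) 14 of 25 members were higher and 11 lower, with log2 changes of 0.29 for the Rac GTPase gene RAC2, 0.20 for WASF2, -0.22 for the kinase gene PAK2 and -0.17 for WASF1. Without the array labelled Tiam1 siRNA of passage 29 RAC2 had 0.18 and PAK2 -0.13, without both arrays of that passage WASF2 had 0.13, and without background correction WASF1 had -0.097. The actin cytoskeleton list had an adjusted p of 0.721, with 0.23 for TPM2, 0.20 for TAGLN, -0.15 for TMSB10 and -0.33 for the membrane-actin linker gene MSN, which was detected on 2 of 3 arrays labelled Tiam1 siRNA. TMSB10 had -0.087 without the untreated array of passage 29, and MSN had -0.19 without background correction. In both of these lists 0 members passed, adjusted over the list alone or over all genes.

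The apoptosis list did not pass (adjusted p = 0.677), with log2 changes of 0.26 for TRADD, 0.22 for BIRC3 and 0.22 for XIAP, which was detected on 1 of 3 untreated arrays and had 0.12 without background correction and 0.14 without the untreated array of passage 29. Neither cell cycle list passed, with adjusted p = 0.353 for S phase and DNA replication and 0.934 for G2 and M phase. E2F2 had 0.26, CDT1 0.17, TYMS 0.15 and RFC3 -0.12 in the first, and PLK1 -0.24, MAD2L1 -0.16, UBE2C 0.13 and ANLN 0.14 in the second. RFC3 and UBE2C turned sign when a gene's probes were averaged, and UBE2C had 0.08 under median scaling. RFC3 had -0.07 without the untreated array of passage 27 and PLK1 -0.14 without that of passage 29. Without both arrays of passage 29 CDT1 had 0.11, TYMS 0.08 and ANLN 0.06, and without both of passage 27 MAD2L1 had -0.09. The type I interferon list had an adjusted p of 0.132, with 0.32 for ISG20, 0.23 for IFI6 (0.10 with the mean of a gene's probes), 0.19 for ISG15 and -0.30 for XAF1. Without background correction ISG20 had 0.20 and XAF1 -0.18. In these 4 lists 0 members passed, adjusted over the list alone or over all genes.

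Of 7 cell type marker lists, 0 passed. The photoreceptor list had an adjusted p of 0.216, with 19 of 29 members lower. Its members included PDE6A with 0.37, CNGB1 with 0.31, GNGT2 with -0.29 and NRL, a photoreceptor transcription factor gene, with -0.38. Without the array labelled Tiam1 siRNA of passage 29 NRL had -0.20, and without both arrays of that passage NRL had -0.12 and GNGT2 -0.17. CNGB1 had 0.18 without the array labelled Tiam1 siRNA of passage 25. Without the array labelled Tiam1 siRNA of passage 25 this list passed, shifting downward (adjusted p = 0.00489). The Muller glia and astrocyte list had an adjusted p of 0.0545, 0.0218 without the untreated array of passage 25 and 0.371 without a detection filter, and it passed in 7 of 21 alternatives. It held 6 measured genes, of which TIMP3 is shared with the adhesion list and passed adjusted over the list alone. The remaining marker lists had adjusted p-values of 0.149 for stromal and endothelial, 0.258 for other retinal neurons, 0.283 for retinal progenitors, 0.473 for retinal pigment epithelium and 0.806 for immune cells.

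The other lists did not pass either. Their adjusted p was 0.112 for oxidative stress and metal response, 0.133 for oxidative phosphorylation and for histone genes, 0.149 for cytosolic ribosomal proteins and 0.258 for the unfolded protein response. It was 0.389 for NF-kB and inflammatory genes and for the integrated stress response, 0.424 for hypoxia and glycolysis, 0.677 for RNA interference machinery and for autophagy, and 0.721 for the Wnt pathway. It was 0.774 for heat shock, 0.806 for immediate early genes and 0.873 for cholesterol biosynthesis. Cytosolic ribosomal proteins and oxidative phosphorylation passed, shifting downward, under median scaling, with adjusted p-values of 0.00442 and 0.00379, and on the authors' value table, with 0.00181 and 0.00164. The ribosomal list also passed with the mean of a gene's probes (adjusted p = 0.0477). Oxidative phosphorylation also passed without the untreated array of passage 25 (adjusted p = 0.0218) and without both arrays of that passage (0.0245), and the integrated stress response list passed, shifting upward, without the untreated array of passage 27 (adjusted p = 0.0149).

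The arrays themselves differed most by 1 untreated array. The first principal component of the tested genes held 36.5% of the variance and placed the untreated array of passage 29 at 21.4, with the other arrays between -8.54 and 0.919. The SD over genes of its differences from the other untreated arrays was 0.250, against 0.172 to 0.202 for the other arrays in their own groups.

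**Figure D3:**
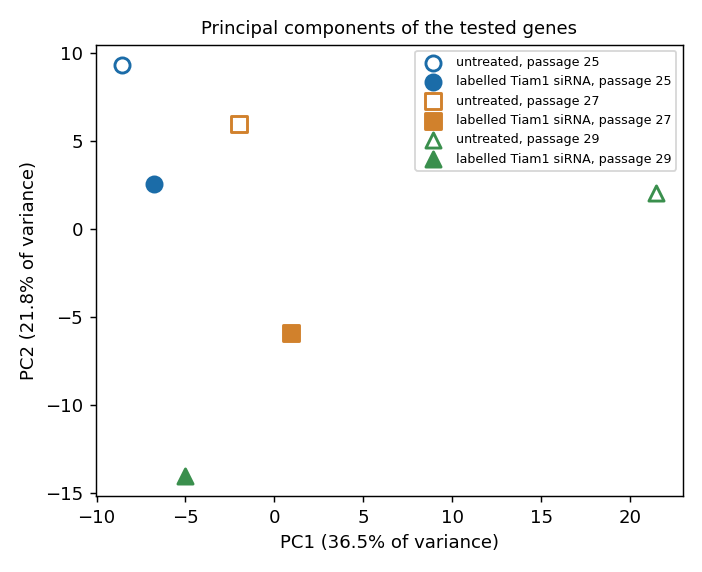
First principal component (x axis, 36.5% of variance) and second (y axis, 21.8%) of the normalized log2 signal of 12866 genes, with open symbols for untreated arrays, filled symbols for arrays labelled Tiam1 siRNA and one marker shape per passage. The untreated array of passage 29 lies at 21.4 on the first component, apart from the other arrays.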

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

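The count of genes past an adjusted p of 0.05 was 0 under every alternative run, as was the count of list members, and it was also 0 with a threshold of 0.1, with 1.5-fold added, and with every kept probe tested singly, which was chosen after seeing the data. At an unadjusted p under 0.05, 748 genes became 1721 without a detection filter (with more genes tested), 1187 with array weights and 478 without the array labelled Tiam1 siRNA of passage 29. The arrays share a passage number, and nothing says that one culture was split between the groups. The deviations from the group means correlated across genes at 0.265, 0.0163 and 0.000803 between the arrays of passages 25, 27 and 29, and, across the groups, only those of passage 25 correlated best with each other. With passage as a block, 0 genes passed, 855 had an unadjusted p under 0.05 and the smallest adjusted p was 0.604. The block brought the Muller glia and astrocyte list past the threshold (adjusted p = 0.0477; marker lists passed: 1) and changed no other call. TIAM1 kept its sign in 21 of 21 alternatives, from -0.27 to -0.0082, and its unadjusted limma p ranged from 0.0143 without the untreated array of passage 29 to 0.960 without both arrays of passage 25. The p53 list passed in 21 of 21 alternatives to the fit (adjusted p from 1.27e-05 to 0.0224), the proteasome list in 17, the MYC list in 15 and the adhesion list in 14. The number of lists passed, 4 of 32, became 7 under median scaling and 0 with an estimated correlation or fry, and ranged from 1 to 6 when arrays or passages were left out. Marker lists passed rose from 0 to 1 with median scaling, detection on all 6 arrays, the mean of a gene's probes, array weights or passage as a block, and ranged from 0 to 1 when arrays or passages were left out. With the mean of a gene's probes the log2 change turned sign for ARHGEF7 (-0.0187), RFC3 (0.0171) and UBE2C (-0.00257). The cause of these changes was not tested. The log2 change of 39 of 64 named genes moved by over 1.5 times, or turned, under at least 1 alternative (TIAM1 not counted). Of 1336 values for these 64 genes, 1333 kept their direction. No gene passed in any fit, so this counts direction alone. Of 671 values for lists, 638 stayed on the same side of the threshold, 17 no longer passed and 16 newly passed. Direction was not compared for lists that passed in neither fit. The difference in detected probes ranged from -421 to 11.7 when arrays were left out. At a detection p under 0.05 it turned sign, to 54. Slide as a block was not run, since no slide was read from the files. Genes near the background, such as GET3, are limited by signal over background.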

Other observations

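The tests of the p53 list without the untreated array of passage 29, of swapped arrays and of a shared state of passage 29, and all tests of the immediate early list were chosen after the values were seen. In fry's test for change in either direction the oxidative stress and metal response list had an adjusted p of 0.000321, while its directional fry adjusted p was 0.243. Of its members 11 were higher and 11 lower, and those with an unadjusted limma p under 0.05 were 4 higher and 0 lower. Adjusted over the list alone, 2 of 22 members passed, MT1F (log2 change 0.70) and MT1A (0.39, list-alone adjusted p = 0.0454), and FTH1, the ferritin heavy chain gene, had 0.27. Copies of the metallothionein family are near-identical, so which member a probe reads is uncertain. Single members of other lists also passed adjusted over the list alone in limma. These were ELAVL3 (0.50) and POU4F2 (0.36) among retinal neuron genes, BAG3 (0.39) among heat shock genes and H2BC4 (-0.40) among histone genes, and none passed over all genes.

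At passage 29 the growth-factor-responsive transcription factor genes EGR1, FOS and FOSB differed from passages 25 and 27 by -1.39, -1.11 and -0.999 on the log2 scale, with treatment in the limma fit. This was not particular to passage 29 among arrays labelled Tiam1 siRNA, where EGR1 was at 9.41, 7.65 and 7.45 at passages 25, 27 and 29, FOS at 11.02, 9.40 and 9.31 and FOSB at 9.72, 8.28 and 8.08. Their adjusted p-values were 0.548, 0.574 and 0.574, and 0 genes passed while 1069 had an unadjusted p under 0.05. Camera on the immediate early list, which holds these 3 genes, gave an unadjusted p of 0.0432 (adjusted p = 0.208), and 0.233 with an estimated correlation. For the same contrast 5 other lists had a smaller unadjusted p and 0 passed. Without the 3 genes the unadjusted camera p was 0.446 over 19 members, with a median of -0.0136 (SD 0.133) against -1.11 for the 3 genes. A fall as large across the list is argued against by that median, and a smaller shift stays open.

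TIAM1 did not pass the test, with a log2 change of -0.11. Compression by background and offset is argued against as hiding a loss of 50% of the transcript, which would have given -0.85 on this scale. That lies below the interval's lower end of -0.40, at which 73.0% of the transcript would be left, and a smaller loss stays open. Both figures take all corrected signal as TIAM1, so background particular to this probe was not tested. Like the interval, they take the labels of passage 29 as given and include its untreated array, which stands apart. Without both arrays of that passage the log2 change was -0.27, so the 73.0% holds only if those labels are right. A swap of both arrays of passage 29 stays open. With those labels exchanged, 575 genes had an unadjusted limma p under 0.05, against 748 as labelled. In camera at the preset correlation 2 lists passed, against 4 as labelled. Other splits that break the labels gave up to 1108 genes and up to 5 lists, so these counts decide nothing. The p53 list's median difference at that passage lay at percentile 99.99 of 10000 expression-matched random lists, but this sets 1 array against 1 that stands apart, so it decides nothing. A single wrong label, or silencing seen in the protein alone, was not tested and stays open.

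The p53 target list was higher by label at each passage. The shift did not rest on the untreated array of passage 29 alone. Without that array the unadjusted camera p at the preset correlation was 1.11e-05. A general drift of higher variance genes is argued against by random lists matched on expression and spread. Counting the list itself, the share that reached its mean t was 1e-04, the smallest these draws can give. Neither test bears on whether treatment caused the shift. Random lists do not carry the correlation among p53 targets. With that correlation estimated, the unadjusted camera p was 0.0391 and the adjusted p was 0.609. The splits of the arrays, 10 in all, are too few for a share under 0.05. The real split had a camera value of 7.14e-06, reached in 1 of 10 splits, and the smallest among the others was 0.00252. The list also passed in the split with the labels of passage 25 exchanged. It passed again with both arrays of passage 25 and the untreated array of passage 27 set against the rest. Passing at the preset correlation thus also occurred outside the split by label. In both of these other splits most arrays stay grouped as labelled. A shift by label could carry into them, so their passing decides nothing. Tiam1 silencing, siRNA in general and transfection all go with the label and stay open.

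For the counts the splits are also too few for a share under 0.05. The real split gave 748 genes at an unadjusted p under 0.05 and the highest other 1108, with 3 of 10 splits giving as many, and it gave 4 lists and the highest other 5, with 4 of 10 giving as many. The split in which the labels of passage 25 were exchanged passed the same 4 lists as the real split and oxidative phosphorylation.

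The untreated array of passage 29 stood apart from the others. Its deviations ran against genomic gene span, known for 87.6% of genes (Spearman correlation across genes -0.289, genes not being independent replicates), but after removing that trend the SD was 0.235, above the 0.192 of the next array. After removing a trend with intensity it was 0.2454, against 0.2455 before and 0.197 for the next array. The arrays were already quantile normalized, so little such trend was left to remove and this test says little. A state shared by both arrays of the passage is argued against as the whole cause by a correlation of deviations of 0.000803. A difference in RNA quality or in that culture alone may remain, and no biological explanation was tested.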
